A study of Mus musculus with 11 samples.

How the data were processed

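The study's material was genomic DNA of ILC2 and γδ T cells sorted from mouse lung, per the labels' protocols, and the series title describes targeted sequencing of the TCRγ locus. The authors deposited 1 clonotype table per library, 11 in all. Each holds a count of reads per clonotype as deposited, with no normalization, and a fraction, which the authors give and which equals the count over the library's total. Other deposited columns give the junction's nucleotides and amino acids, the V and J segments, and the positions of the V end and J start, which count from 0. The file names call the tables corrected. The submitters' processing notes name bcl2fastq and mm10, with no role or version. The aligner, clonotype caller, primers, correction and number of sorted cells are not given in the sources used here. Nothing says whether molecular identifiers were used, so that counts are described as reads.

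Groups and replicate numbers came from the sample titles. Productive means that the deposited amino acid sequence has no frameshift or stop mark. Inserted bases are those between V end and J start, and the 32 clonotypes without a V end were left out of that measure. Clonotype numbers are log2 of the number expected when each library is thinned to 28162 reads. Gene coordinates came from the RefSeq gene table of GRCm38.p6, the assembly that mm10 names.

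Each of the 6 measures was tested with an exact permutation test, 2-sided by absolute size. Cell type labels were permuted within each target (200 arrangements), and the statistic was the mean over the 2 targets of the ILC2 minus γδT difference. Benjamini-Hochberg adjustment covered the 6 measures, with a threshold of 0.05. The test treats the 11 libraries as independent, although the labels do not say whether same-numbered libraries of the 2 targets share animals or DNA. The difference between the targets was tested by permuting target labels within cell type. The named clonotypes are, for each target, the 5 with the highest mean share of reads in each cell type, the 5 with the largest positive and the 5 with the largest negative difference among those in at least 2 libraries, and up to 5 found in all ILC2 libraries. The rule took 14 clonotypes for Vγ2 and 11 for Vγ1.2, of which the text gives a part.

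Groups, measures, tests, lists, the rule for named clonotypes and the alternatives were fixed before the data were examined, except 3 alternatives added afterwards: productive clonotypes that also start with C and end with F, and inserted bases with each clonotype counted once, either over 0.1% of reads or within the main V-J pair. Sums over the nucleotide forms of a junction were also added afterwards. Alternatives left out clonotypes with a single read, under 0.1% of reads, outside the main V-J pair or (from ILC2 alone) found in both cell types. Others merged clonotypes by nucleotides alone or within 1 mismatch of one at least 20 times as abundant, used medians, blocked by replicate number, took same-numbered libraries as 1 animal, or left out each library in turn. Measures were also redefined (productive from the nucleotides, log odds, no thinning, thinning to 2816 reads, inverse Simpson index, the 3 largest clonotypes, at most 2 inserted bases, shares of clonotypes). A planned beta-binomial model in glmmTMB 1.1.9 (R 4.3.3) did not converge, and its value was not used.

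In 100000 seeded draws, each ILC2 clonotype with 0.1% of reads or more was made productive, or free of inserted bases, with the mean share of γδT reads. The draws were repeated, as a later choice, with each distinct ILC2 clonotype drawn once over libraries, and with the share of γδT clonotypes in place of reads. A difference was taken to pass a bound when it lay beyond it by 2 standard errors, a choice made after the values were seen. An excess of clonotypes near the median read count was taken as a mark of few templates only if no γδT library of that target passed the same bound of 50%, also decided after the values were seen. Tested on simulated data, the combined test passed 0.05 in 4.7% of 1000 designs with no difference, and a true difference of -25 points in the productive share of clonotypes came back as -24.98. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.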

Results

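The data were clonotype tables of rearranged T cell receptor γ (TCRγ) genes in genomic DNA from mouse lung. The cells were sorted group 2 innate lymphoid cells (ILC2), lymphocytes of barrier tissues that carry no T cell receptor at their surface, and γδ T cells (γδT), whose receptor includes a TCRγ chain. A clonotype is a junction (CDR3) of 1 nucleotide sequence with its V and J segment. The titles name 2 targets, Vγ2 and Vγ1.2, with 3 ILC2 and 2 γδT libraries for Vγ2 and 3 of each cell type for Vγ1.2, from wild-type C57BL/6 mice. The libraries held 28162 to 106108 reads, so that 3 reads, the limit a count of 0 allows, were 0.00283% to 0.0107% of a library. Vγ2 libraries had 82640, 79097 and 84013 reads in ILC2 and 31357 and 81456 in γδT. Vγ1.2 libraries had 98733, 106108 and 28162 reads in ILC2 and 84716, 92164 and 40536 in γδT. Reads are PCR products, and intervals and limits cover counting error only. The labels do not say that replicates came from separate animals, so that p-values measure the spread between these libraries, which may be technical.

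By reads, the Vγ2 libraries held mainly TRGV4 joined to TRGJ1, and the Vγ1.2 libraries mainly TRGV2 joined to TRGJ2, in both cell types. TRGV4-TRGJ1 took 99.9% ± 0.135 (SD, n = 3) of the Vγ2 reads of ILC2 and 99.3% ± 0.811 (SD, n = 2) of those of γδT. TRGV2-TRGJ2 took 96.9% ± 4.43 (SD, n = 3) of the Vγ1.2 reads of ILC2 and 94.0% ± 3.38 (SD, n = 3) of those of γδT. TRGV3-TRGJ3 took 3.10% ± 4.39 (SD, n = 3) and 4.92% ± 2.77 (SD, n = 3) of the same Vγ1.2 reads. Counted by clonotypes, pairs other than the main one were 12.7%, 48.9% and 37.9% of the Vγ2 ILC2 clonotypes against 2.84% and 1.66% in γδT, and 9.68%, 22.6% and 22.2% of the Vγ1.2 ILC2 clonotypes against 8.25%, 10.1% and 7.43% in γδT. Values per clonotype include them unless stated. On chromosome 13 of GRCm38, Trgv4 lies at 19184981 to 19185506 and Trgj1 at 19210343 to 19210402. Trgv2 lies at 19336573 to 19337026, Trgj2 at 19311245 to 19311304, Trgv3 at 19242845 to 19243301 and Trgj3 at 19257117 to 19257176. The annotation lists them as V or J segments, the coding pieces that are joined during lymphocyte development. The invariant junction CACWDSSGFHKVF of TRGV5 and TRGV6 γδ T cells had 0 reads in the 11 libraries, whose targets were other V segments, so that TRGV5 and TRGV6 each had 0 to 2 reads in any library and the 0 says nothing about this junction in the cells.

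**Figure D1:**
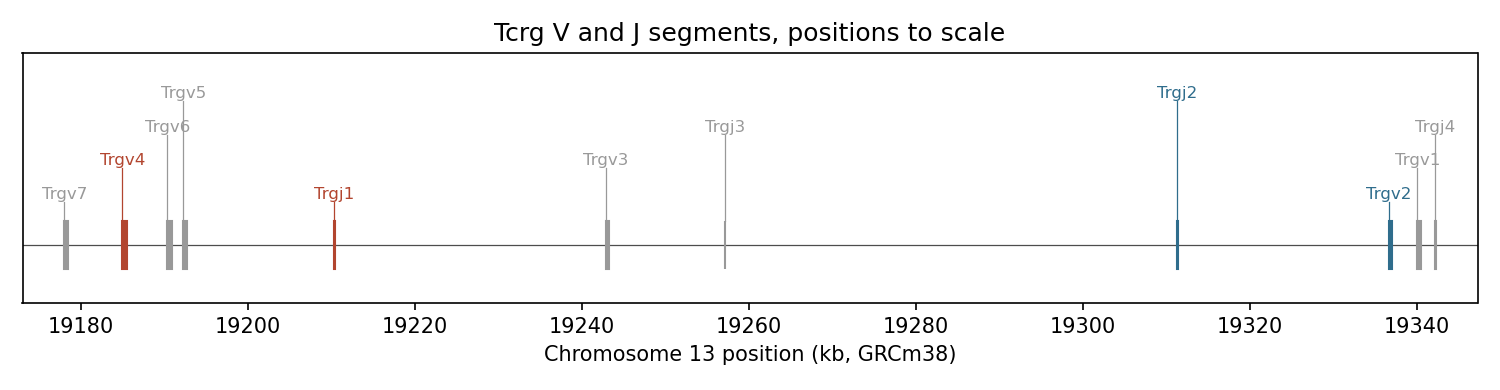
The mouse Tcrg locus on chromosome 13 (GRCm38), with the position in kb on the x axis and each V and J segment as a box at its annotated position. Trgv4 and Trgj1 (red) were joined in most reads of the Vγ2 libraries, Trgv2 and Trgj2 (blue) in most reads of the Vγ1.2 libraries, and the other segments are grey.

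The first comparison asked how varied the TCRγ rearrangements of ILC2 were beside those of γδT. ILC2 libraries held far fewer clonotypes for both targets. Thinning to equal reads does not equalize the rearranged templates that entered the PCR. Fewer clonotypes therefore need not mean less varied rearrangements in the cells. At an equal depth of 28162 reads, the Vγ2 ILC2 libraries had 41.1, 66.5 and 27.6 clonotypes against 1221 and 647 in γδT, and the Vγ1.2 ILC2 libraries had 44.3, 38.2 and 117.0 against 885, 827 and 960.1. The number fell by 4.16 on the log2 scale, or 17.9-fold, over both targets (exact permutation p = 0.005, adjusted p = 0.015, lower in 6 of 6 ILC2 libraries). It was -4.46 within the main V-J pair, which held 48, 45 and 36 clonotypes in the Vγ2 ILC2 libraries and 1198 and 653 in γδT, before thinning. The log2 difference was -4.39 for Vγ2 and -3.93 for Vγ1.2, and the difference between the targets gave an exact permutation p = 0.54. The effective number of clonotypes, the exponential of the Shannon entropy, was 21.0-fold lower in ILC2 (log2 difference -4.39, exact permutation p = 0.005, adjusted p = 0.015), with 8.05 to 32.5 in ILC2 and 373 to 628 in γδT. An adjusted p of 0.11 followed with medians in place of means for the effective number (log2 difference -4.13). Without clonotypes under 0.1% of reads, the log2 difference was -3.19 for the number and -2.54 for the effective number, and by the inverse Simpson index it was -2.93, each with an adjusted exact p of 0.015. Leaving the clonotypes of both cell types out of ILC2 alone gave -5.33 and -5.93, a setting that takes clonotypes from one side and so does not test the call. The smallest p of the combined test is 0.005 and that of a test within 1 target is 0.1, which cannot pass 0.05.

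The largest clonotype also took more of the ILC2 reads, a share that depends on the number of clonotypes. The most abundant clonotype held 8.94% ± 5.05 (SD, n = 3) of the Vγ2 reads in ILC2 and 4.45% ± 1.30 (SD, n = 2) in γδT, and 15.6% ± 1.36 (SD, n = 3) against 5.58% ± 0.623 (SD, n = 3) of the Vγ1.2 reads. The share rose by 7.27 percentage points over both targets (exact permutation p = 0.02, adjusted p = 0.03). Replicate 2 of the Vγ2 ILC2 libraries, at 3.43%, lay below both γδT libraries, so that the direction held in 5 of 6 ILC2 libraries. The difference was 4.10 points without clonotypes under 0.1% of reads (exact permutation p = 0.07, adjusted p = 0.07) and 7.91 points with medians (exact permutation p = 0.1, adjusted p = 0.1). It was 16.4 points with the clonotypes of both cell types left out of ILC2 alone, which takes reads from one side only. Without replicate 1 or 3 of the Vγ2 ILC2 libraries or replicate 2 of the Vγ1.2 ILC2 libraries, it was 6.99, 6.17 and 6.98 points, each with an adjusted exact p of 0.05. A large share need not mean that 1 clonotype dominated. In Vγ2 ILC2, 24 of 30, 30 of 33 and 8 of 8 clonotypes with 0.1% of reads or more lay within 15% of their median reads. The largest of the 8 in replicate 3 held 13.3%. In Vγ1.2 ILC2, 3 of 34, 5 of 26 and 13 of 34 lay within that range.

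**Figure D2:**
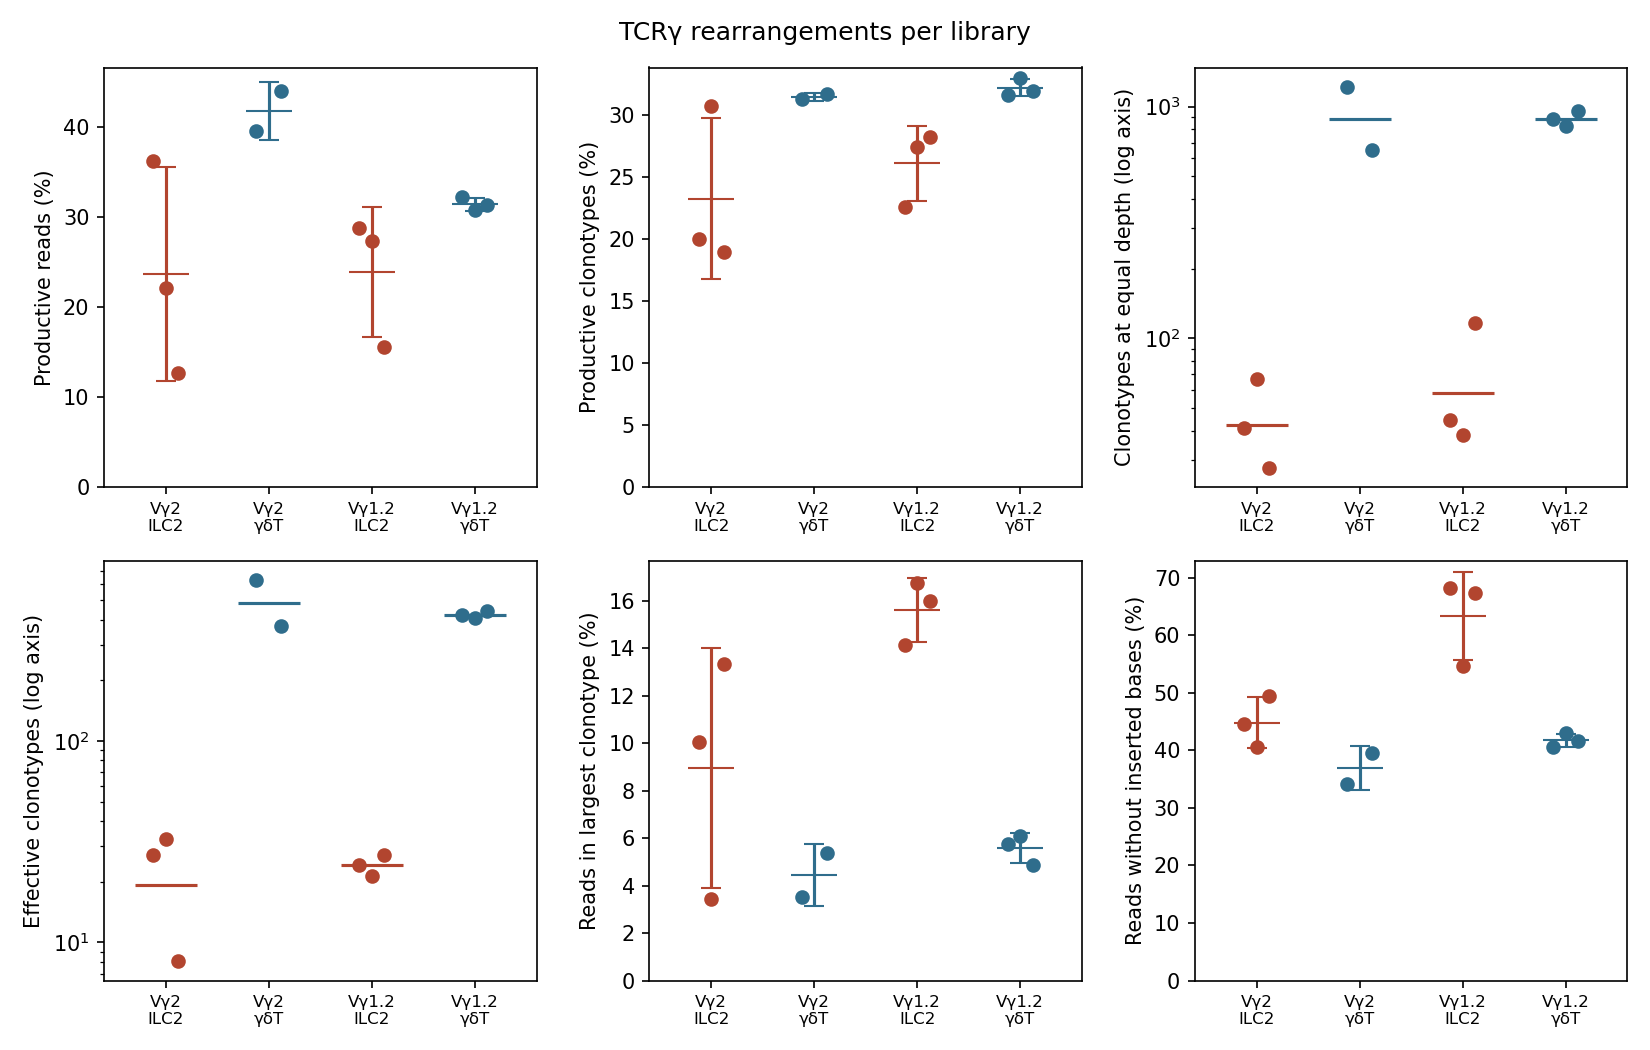
The 6 measures per library, with 1 point per library, ILC2 in red and γδT in blue, and the target and cell type on the x axis. Linear panels show the mean with its SD, and the panels of clonotype numbers have log axes and a line at the mean of the log2 values; ILC2 libraries had 27.6 to 117.0 clonotypes at equal depth and γδT libraries 647 to 1221.

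Named clonotypes differed in how the cell types shared them, and values are for 1 nucleotide form unless a sum over forms is named. In the Vγ2 libraries the productive junction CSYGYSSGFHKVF (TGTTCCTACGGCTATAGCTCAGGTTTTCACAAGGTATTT) was found in all 5 libraries, at 8.57% ± 5.01 (SD, n = 3) of reads in ILC2 and 3.93% ± 0.571 (SD, n = 2) in γδT. Its values were 10.1%, 2.98% and 12.7% in ILC2 and 3.53% and 4.33% in γδT, so that the groups overlapped for this form. Summed over its 4 nucleotide forms, the junction took 10.1%, 6.22% and 12.7% in ILC2 and 4.60% and 5.81% in γδT. The difference of 4.64 points for the single form was 2.58 without ILC2 replicate 3 and 7.43 without ILC2 replicate 2. Of the named Vγ2 clonotypes, the out-of-frame CSYGI*L_GFHKVF had the largest difference, 5.32 points, and the out-of-frame CSYG*I*_SGFHKVF, CSYGEP_FHKVF, CSYGIA_GFHKVF and CSYGYIA_GFHKVF followed the productive junction with 4.41, 4.36, 3.99 and 3.82 points. In ILC2 replicate 3 these 5 took 13.3%, 13.1%, 13.1%, 12.7% and 12.2% of reads, and without that library their differences were 1.41, 0.577, -0.00123, -0.235 and 0.0312 points. Leaving out ILC2 replicate 1 or 2 in turn gave 5.28 to 8.09 points. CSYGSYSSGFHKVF (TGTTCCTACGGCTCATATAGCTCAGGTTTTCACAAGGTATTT), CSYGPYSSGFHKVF (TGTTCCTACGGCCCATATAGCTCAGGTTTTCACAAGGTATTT), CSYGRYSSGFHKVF (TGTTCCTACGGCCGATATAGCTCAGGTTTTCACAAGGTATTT) and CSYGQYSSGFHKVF (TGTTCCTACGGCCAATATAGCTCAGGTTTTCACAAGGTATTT) were found in both γδT libraries, at 1.80% ± 1.09, 1.29% ± 0.00231, 1.08% ± 0.860 and 0.897% ± 0.0597 of reads (SD, n = 2), and these forms had 0 reads in the 3 ILC2 libraries. Another form of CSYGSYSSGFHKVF had 2887 reads, or 3.49%, in ILC2 replicate 1, while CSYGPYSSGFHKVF, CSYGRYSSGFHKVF and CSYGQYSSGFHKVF had 0 ILC2 reads in any of the 5, 8 and 4 forms found. These forms were named for their negative difference. The Vγ2 ILC2 libraries held only 30, 33 and 8 clonotypes with 0.1% of reads or more. Forms at such shares may therefore be missed by sampling, and 0 reads does not show that they were absent from the cells. The difference for the named form of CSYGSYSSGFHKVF was -1.03 without γδT replicate 2, and that for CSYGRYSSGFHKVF was -0.471 without γδT replicate 1 and -1.69 without γδT replicate 2. Junctions of the pattern CSYGxYSSGFHKVF, with any residue at x, took 7.57% ± 10.7 (SD, n = 3) of Vγ2 reads in ILC2 and 17.2% ± 5.10 (SD, n = 2) in γδT. The values were 19.8%, 2.90% and 0.00357% in ILC2 and 13.6% and 20.8% in γδT, so that the groups overlapped. The difference of -9.61 points was -15.7 without ILC2 replicate 1, -5.83 without ILC2 replicate 3 and -6.01 without γδT replicate 2. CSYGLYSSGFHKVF had 5 nucleotide forms in these libraries, 2 of them among the named clonotypes. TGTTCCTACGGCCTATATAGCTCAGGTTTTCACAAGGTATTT, found in all 5 libraries, took 2.12% ± 1.85 (SD, n = 3) of reads in ILC2, where replicate 3 held 3 reads, and 1.153% ± 0.531 (SD, n = 2) in γδT. Its difference of 0.963 points was 0.297, 0.573 and 2.02 without ILC2 replicate 1, 2 or 3, and 0.588 without γδT replicate 1. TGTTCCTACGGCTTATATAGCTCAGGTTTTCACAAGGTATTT took 6.37% in ILC2 replicate 1, had 0 reads in the other ILC2 libraries, and took 3.93% ± 2.04 (SD, n = 2) in γδT. Its difference of -1.81 points was -3.93 without ILC2 replicate 1, -0.744 without ILC2 replicate 2 or 3, -3.25 without γδT replicate 1 and -0.367 without γδT replicate 2. In the Vγ1.2 libraries the most abundant clonotypes were out-of-frame. CAVWIA_GFHKVF, where _ marks the frameshift, was found in all 6 libraries, at 12.9% ± 4.51 of reads in ILC2 and 4.65% ± 1.81 in γδT (SD, n = 3 each). CAVWI*L_GFHKVF, also in all 6, took 9.32% ± 5.78 and 5.45% ± 0.490 (SD, n = 3 each). Its values in ILC2 were 5.53%, 6.45% and 16.0%, and the difference of 3.88 points was 0.547 without ILC2 replicate 3. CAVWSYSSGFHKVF (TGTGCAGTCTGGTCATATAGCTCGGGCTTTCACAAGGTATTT) and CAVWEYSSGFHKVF (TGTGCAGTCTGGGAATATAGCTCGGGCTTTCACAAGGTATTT), both productive, had 0 reads of these forms in ILC2 and 1.25% ± 1.46 and 0.646% ± 0.0236 in γδT (SD, n = 3). The difference of -1.25 points for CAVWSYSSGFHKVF was -0.408 without γδT replicate 3. Another form of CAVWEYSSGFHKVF had 2352 reads, or 2.22%, in ILC2 replicate 2. The limit of sampling holds here too, as the Vγ1.2 ILC2 libraries held 34, 26 and 34 clonotypes with 0.1% of reads or more. No single clonotype was tested, since an exact permutation test of 3 libraries against 3 or 2 cannot pass 0.05.

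**Figure D3:**
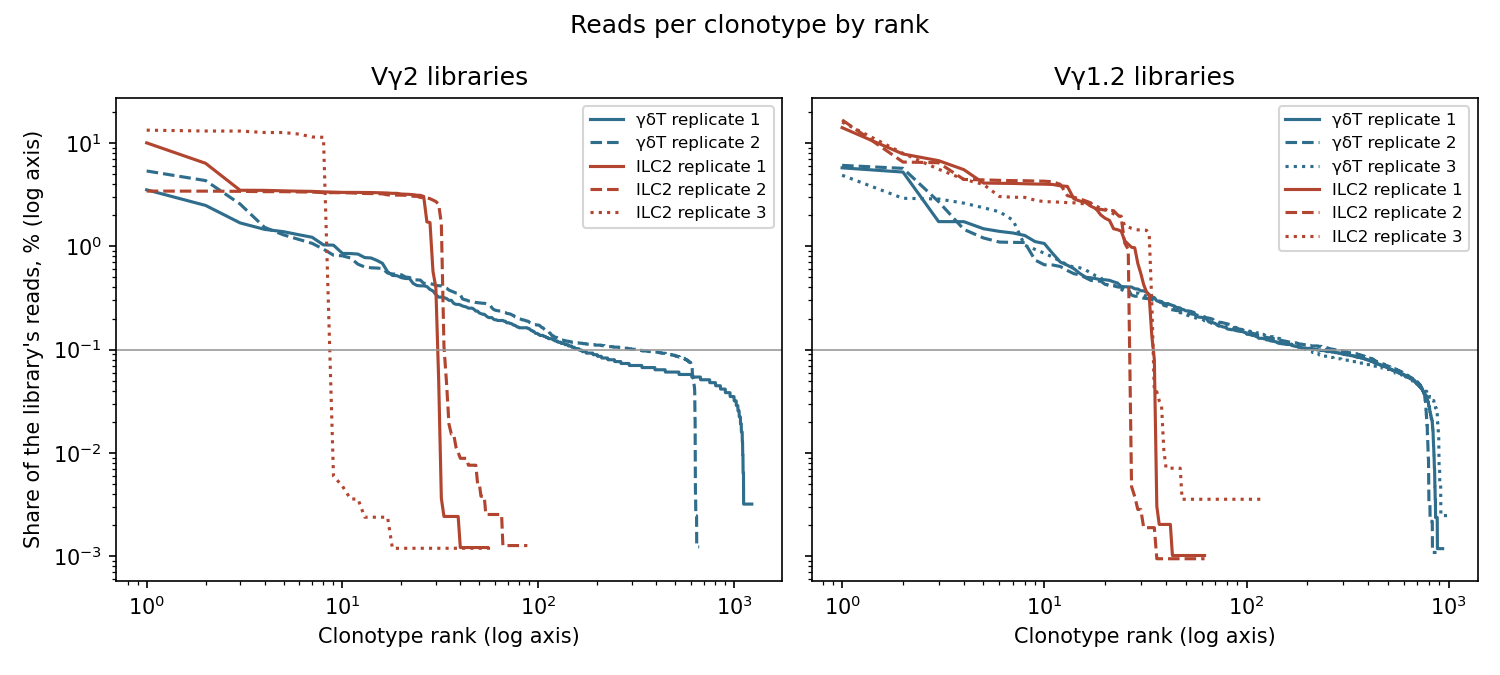
Share of a library's reads (log axis) against clonotype rank (log axis), for Vγ2 on the left and Vγ1.2 on the right, with 1 line per library and a grey line at 0.1% of reads. ILC2 libraries (red) fell below 0.1% after 8 to 34 clonotypes and γδT libraries (blue) after 161 to 315.

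The next comparison asked how often the rearrangements could encode a TCRγ chain. A clonotype was productive when its junction was in frame and had no stop codon. Productive rearrangements took 23.7% ± 11.9 (SD, n = 3) of Vγ2 reads in ILC2 and 41.8% ± 3.19 (SD, n = 2) in γδT, and 23.9% ± 7.26 (SD, n = 3) against 31.4% ± 0.739 (SD, n = 3) of Vγ1.2 reads. The share of reads fell by 12.8 percentage points over both targets (exact permutation p = 0.045, adjusted p = 0.045), and lay below every γδT library of the target in 6 of 6 ILC2 libraries. Counting each clonotype once, 23.2% ± 6.49 (SD, n = 3) of Vγ2 clonotypes were productive in ILC2 and 31.4% ± 0.284 (SD, n = 2) in γδT, and 26.1% ± 3.05 against 32.2% ± 0.716 (SD, n = 3 each) for Vγ1.2. This share fell by 7.16 points (exact permutation p = 0.035, adjusted p = 0.042, lower in 6 of 6 ILC2 libraries). It was -4.25 points without clonotypes of a single read and -10.6 without clonotypes under 0.1% of reads (exact permutation p = 0.005, adjusted p = 0.01 for both). The filter at 0.1% removed 27.4% to 51.6% of γδT reads but at most 0.455% of ILC2 reads, so that the larger gap is not a stronger result. Within the main V-J pair the shares were 23.4% ± 2.26 (SD, n = 3) against 31.0% ± 0.704 (SD, n = 2) for Vγ2 and 25.2% ± 1.94 against 32.0% ± 1.12 (SD, n = 3 each) for Vγ1.2. Out-of-frame junctions took 70.1% ± 17.8 (SD, n = 3) and 47.9% ± 1.74 (SD, n = 2) of Vγ2 reads and 73.8% ± 3.78 and 66.8% ± 0.820 (SD, n = 3 each) of Vγ1.2 reads, in ILC2 and γδT. The Vγ2 difference of 22.2 points was 13.6 without ILC2 replicate 3. The call for reads lay at the threshold. It had an adjusted exact p of 0.05 for the main V-J pair alone, 0.09 without the clonotypes of both cell types in ILC2, 0.06 with medians, and 0.055 both on the log odds scale and with C and F required at the ends, the last chosen after seeing the data. For Vγ1.2 alone the difference of -7.51 points was -3.34 without ILC2 replicate 3. Over both targets it was -11.7 points without replicate 2 of the Vγ2 γδT libraries (adjusted exact p = 0.113), -10.7 without replicate 3 of the Vγ1.2 ILC2 libraries (0.08), and -12.6, -13.0 and -12.8 without replicate 1, 2 or 3 of the Vγ1.2 γδT libraries (0.05 each).

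**Figure D4:**
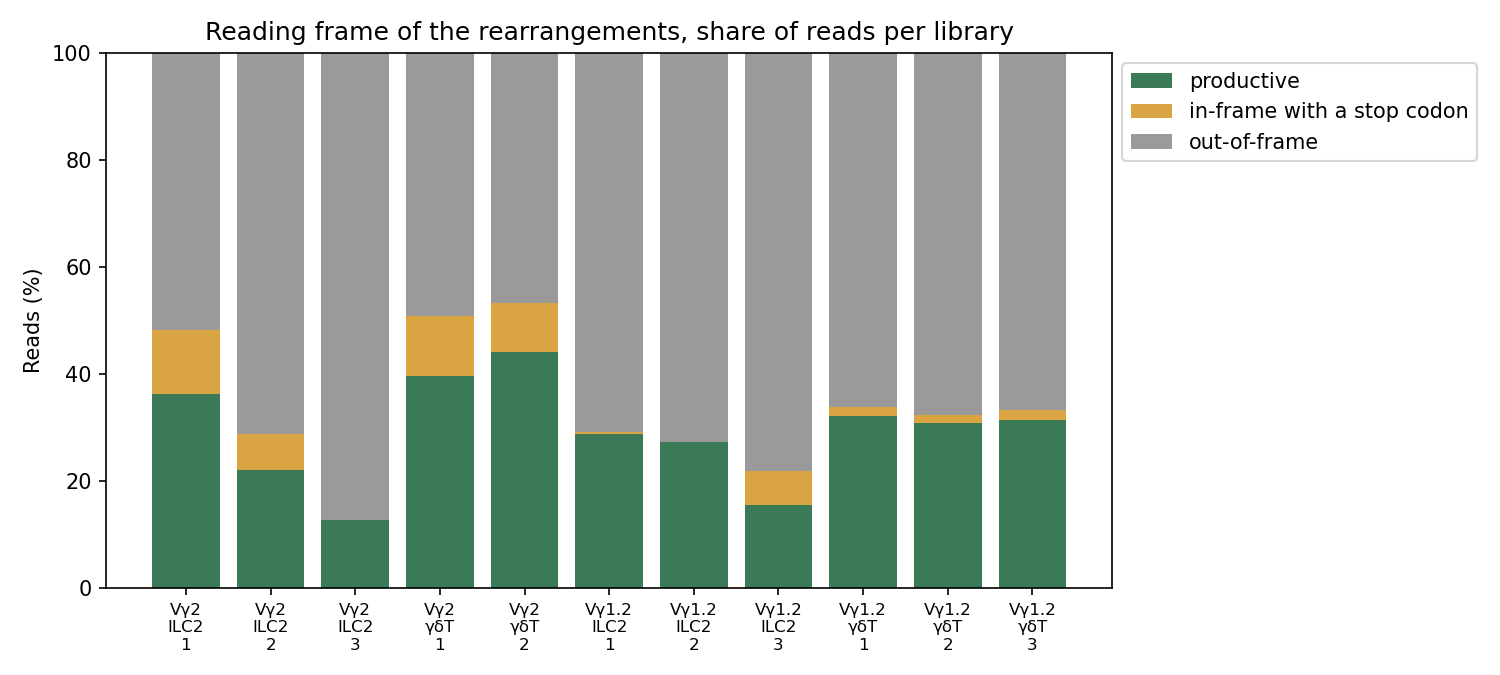
Share of reads (%) in productive, in-frame with a stop codon and out-of-frame rearrangements, as a stacked bar for each of the 11 libraries, named by target, cell type and replicate. Productive reads ranged from 12.7% to 36.3% in ILC2 and from 30.8% to 44.1% in γδT.

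The last measure was the share of reads joined with no base between the V and J segments, as a measure of bases added during joining. It was 44.8% ± 4.42 (SD, n = 3) in ILC2 and 36.9% ± 3.85 (SD, n = 2) in γδT for Vγ2, and 63.4% ± 7.62 against 41.8% ± 1.19 (SD, n = 3 each) for Vγ1.2. The share rose by 14.8 percentage points over both targets (exact permutation p = 0.01, adjusted p = 0.02, higher in 6 of 6 ILC2 libraries). The read-weighted difference was lost without clonotypes under 0.1% of reads, a filter that acted mainly on γδT. It raised the γδT share from 36.9% to 52.6% for Vγ2 and from 41.8% to 55.2% for Vγ1.2. The ILC2 shares with this filter were 44.8% and 63.5%, so that the loss came from the γδT side. Without clonotypes under 0.1% of reads, which removed 27.4% to 51.6% of γδT reads and 0.0490% to 0.455% of ILC2 reads, the difference was 0.252 points (exact permutation p = 0.95, adjusted p = 0.95), the mean of -7.80 for Vγ2 and 8.30 for Vγ1.2. With the same filter and each clonotype counted once, an alternative chosen after seeing the data, it was 12.8 points (standard error 4.12, exact permutation p = 0.02, adjusted p = 0.03), 8.48 for Vγ2 and 17.2 for Vγ1.2. Without the clonotypes that ILC2 shared with γδT, left out of ILC2 alone, it was -16.0 points (exact permutation p = 0.14, adjusted p = 0.14). Per clonotype, 40.5% ± 2.00 (SD, n = 3) of Vγ2 clonotypes in ILC2 and 19.1% ± 3.68 (SD, n = 2) in γδT had no inserted base, and 43.2% ± 5.96 against 24.2% ± 1.90 (SD, n = 3 each) for Vγ1.2. Within the main V-J pair these were 37.4% ± 4.17 (SD, n = 3) against 18.7% ± 3.71 (SD, n = 2), and 44.7% ± 6.34 against 23.6% ± 2.04 (SD, n = 3 each).

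Most ILC2 reads lay in clonotypes that γδT libraries also held. They were 63.5%, 57.6% and 77.1% of reads in the Vγ2 ILC2 libraries and 83.7%, 73.6% and 78.0% in the Vγ1.2 ILC2 libraries. Of γδT reads, 15.9% and 20.2% for Vγ2 and 29.6%, 30.5% and 31.5% for Vγ1.2 lay in clonotypes that ILC2 libraries held. These shares were not tested, since the number of libraries and clonotypes to share with differed. A single read in the other cell type counted as sharing, although without single-read clonotypes the ILC2 means were still 66.1% (Vγ2) and 75.6% (Vγ1.2). Among ILC2 clonotypes with 0.1% of reads or more, shared ones had fewer inserted bases on average in every library. Library means were 0.56 to 1.19 in shared and 2 to 4 in unshared clonotypes. Whether sharing reflects a common origin of the cells was not tested. For none of the 6 measures did the difference between the 2 targets pass the test (exact permutation p = 0.2 to 0.695, adjusted p = 0.51 to 0.695).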

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

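The tests of read depth, of the read levels of the Vγ2 ILC2 clonotypes, of the reads held by rare ILC2 clonotypes, of chance with the share of γδT clonotypes or each distinct clonotype drawn once, of chance in inserted bases per target and of inserted bases with both cell types filtered alike were chosen after the result was seen. Reads of the other target's V-J pair exceeded 3 reads, the limit a count of 0 allows, in 8 libraries. TRGV2-TRGJ2 had 9, 200 and 23 reads in Vγ2 ILC2 replicates 1, 2 and 3 and 364 and 19 reads in Vγ2 γδT replicates 1 and 2. TRGV4-TRGJ1 had 15 reads in Vγ1.2 ILC2 replicate 2, and 14 and 43 reads in Vγ1.2 γδT replicates 1 and 2. Over the 11 libraries, 153 of 165 such clonotypes were also found in libraries of their own target.

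Fewer clonotypes in ILC2. Lower read depth is argued against as the whole cause, since the log2 difference was -4.16 at equal depth. Of Vγ2 ILC2 clonotypes with 0.1% of reads or more, 87.3% (62 of 71, exact 95% interval 77.3% to 94.0%) lay within 15% of their library's median read count. In the γδT libraries 20.5% and 61.9% did, so that sharing a level was not particular to ILC2. The levels themselves differed. Clonotypes near the median had a mean of 2723, 2515 and 10493 reads in ILC2, and library totals were 30.3, 31.4 and 8.01 times that mean. In γδT the means were 50.6 and 89.7 reads, and the totals 620 and 908 times the mean. The γδT shares therefore do not count against few templates in ILC2. For Vγ1.2 the share was 22.3% in ILC2 (21 of 94, 14.4% to 32.1%), an interval that spans the bound of 25% set beforehand, and 27.8%, 38.1% and 32.8% in γδT. The levels differed here too, although only 3, 5 and 13 ILC2 clonotypes lay near the median. Their means were 2444, 3047 and 717 reads in ILC2, against 111, 113 and 60.8 in γδT. Library totals were 40.4, 34.8 and 39.3 times that mean in ILC2 and 766, 818 and 667 times in γδT. For Vγ2 the shared level and the low totals in ILC2 are what few rearranged templates in the PCR would give. They were not taken as a mark of few templates, since Vγ2 γδT replicate 2, at 61.9%, also passed the bound of 50%. That rule was decided after the values were seen. Few rearranged templates therefore remain open for both targets. Whether they would reflect few sorted cells or rarer rearrangement in ILC2 was not tested, and sorted cell numbers are not given in the sources used here.

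Lower productive share of reads in ILC2. For Vγ2, chance among few clonotypes is argued against as the cause of the whole difference in reads: with the share of γδT reads (41.8%), 0.0048 of the draws gave a mean as low as the 23.7% observed, and 0.0115 with each distinct clonotype drawn once. With γδT clonotypes with 0.1% of reads or more these were 0.0001 and 0.0008. That filter raised the γδT share to 48.95% and hardly changed ILC2, so that these 2 values add no support. All draws took clonotypes as independent and the γδT share as known, and so do not cover variation between libraries. The exact permutation test over the Vγ2 libraries alone gave p = 0.2, where 0.1 is the smallest possible. Against the lower share of γδT clonotypes (31.4%), each distinct clonotype drawn once, 0.1699 gave a mean as low, and 0.0806 over the same filter, so that chance may account for that smaller gap; for Vγ1.2 the shares of draws were 0.1153 with reads and 0.1985 with clonotypes. Reads from γδT libraries among rare ILC2 clonotypes are argued against, since clonotypes under 0.1% of reads held at most 0.455% of an ILC2 library; the -16.0 points (standard error 4.08) found without them decided nothing, as nearly all reads removed were from γδT. A difference between the cell types remains open as a hypothesis for both targets.

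More ILC2 reads without inserted bases. Against the share of all γδT reads, chance among few clonotypes is argued against over both targets and for Vγ1.2. There 0.0016 and 0.0005 of the draws gave a value as high (0.0103 and 0.0097 with each distinct clonotype drawn once). These draws too took clonotypes as independent and the γδT share as known, and do not cover variation between libraries. Chance may account for the Vγ2 difference in reads (0.1352). Against the lower share of γδT clonotypes, each distinct clonotype drawn once, 0.0004 gave a value as high for Vγ2. With γδT clonotypes of 0.1% of reads or more this was 0.0975 for Vγ2 and 0.0007 for Vγ1.2. With clonotypes of 0.1% of reads or more in both cell types the difference over both targets was 0.252 points, so that the 0.4838 of draws reaching it decided nothing. It was the mean of -7.80 for Vγ2 and 8.30 for Vγ1.2. For Vγ1.2, against the γδT share of 55.2% in this setting, 0.1146 of the draws gave a share as high, and 0.2136 with each distinct clonotype drawn once. Chance may therefore account for the smaller Vγ1.2 difference left by the filter. Counting each clonotype of at least 10 reads once gave 25.5 points (standard error 3.26), past the bound of 5 set beforehand. That count cannot decide whether a few abundant clonotypes carry the difference, since counting once changed the cell types unequally. For Vγ2 the γδT share was 36.9% of reads but 19.1% of all clonotypes, and the ILC2 share 44.8% and 40.5%. With 0.1% of reads or more in both cell types, counting once gave 12.8 points (standard error 4.12), less than 2 standard errors past the bound. The explanation stays open. Among out-of-frame clonotypes alone the difference was 11.9 points (standard error 4.56), 4.86 for Vγ2 and 19.0 for Vγ1.2, within 2 standard errors of the bound, and -4.25 (standard error 5.35) with that filter, so that it stays open whether productive rearrangements alone differed.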

How the results depend on the processing

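The alternatives that also required C at the start and F at the end, and that counted clonotypes once over 0.1% of reads or within the main V-J pair, were chosen after the data were seen. ILC2 minus γδT differences are in percentage points, or log2 for clonotype numbers. With the replicate block (sign flips; exact p = 0.0625, the smallest possible, but 0.125 for the largest clonotype) they were -10.1 for productive reads, -6.10 for productive clonotypes, -4.01 for clonotype number, -4.08 for effective number, 6.17 for the largest clonotype and 13.6 for reads without inserted bases. With same-numbered libraries as 1 animal they were -12.8, -7.16, -4.16, -4.39, 7.27 and 14.8, with exact p = 0.2 for both productive shares and 0.1, the smallest possible, for the others. Neither design can pass 0.05, so that their p-values say nothing about stability. Each value of the replicate block equals the value without Vγ2 ILC2 replicate 3, which has no γδT library of the same number. The shift from the main values is therefore that of leaving out this library, and shows no effect of blocking. A check of pairing gave correlations of same-numbered libraries of -0.176 and -0.151 for Vγ2 and 0.0527, 0.0770 and 0.0284 for Vγ1.2. For Vγ2 the other γδT library gave the exact mirror values, 0.176 and 0.151, so that these are not plain correlations between libraries. For Vγ1.2 each ILC2 library had its highest value with its own number, but the values were small. No pairing can be read from them, and it stays open.

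Productive reads no longer passed 0.05 for the main V-J pair (-12.4), without clonotypes of both cell types in ILC2 (-15.7), with medians (-11.8), as log odds (-0.664) and with C and F required (-13.4). Medians also ended the call for effective number (-4.13) and the largest clonotype (7.91). Leaving out clonotypes under 0.1% of reads ended it for the largest clonotype (4.10) and for reads without inserted bases (0.252, but 12.8 with each clonotype counted once), which reversed to -16.0 without clonotypes of both cell types in ILC2, where the clonotypes removed had fewer inserted bases. The cause of the others was not tested.

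Leaving out 1 library gave -16.0 to -10.1 for productive reads (no longer past 0.05 in 5 of 11), -9.03 to -6.10 for productive clonotypes, -4.39 to -3.93 for clonotype number, -4.58 to -4.08 for effective number, 6.17 to 8.65 for the largest clonotype (3 of 11) and 13.4 to 17.0 for reads without inserted bases. The difference between the targets, never past 0.05, reversed to 3.36 for the largest clonotype and 8.59 for inserted bases without clonotypes of both cell types in ILC2, and ranged from -5.83 to 0.0303 for productive clonotypes, -0.900 to 0.108 for effective number and -0.921 to 0.0593 for clonotype number without 1 library. Shared reads ranged from 72.3% to 80.9% (Vγ1.2 ILC2), 25.004% to 31.0% (Vγ1.2 γδT), 55.7% to 70.3% (Vγ2 ILC2) and 12.3% to 20.2% (Vγ2 γδT) without 1 library, and were 27.5% in Vγ1.2 γδT without single reads. The beta-binomial model could not be fitted.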

Other observations

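Counting clonotypes once over libraries was chosen after the result was seen. Of ILC2 clonotypes with 0.1% of reads or more, 52 of 165 (31.5%, exact 95% interval 24.5% to 39.2%) were in frame, counted once per library. Joining without regard to the reading frame, a hypothesis, gives 1 in 3 if junction lengths fall evenly over the frames, which was not tested. The exact binomial p against that share was 0.68. Counted once over libraries, 47 of 143 were in frame (exact p = 1). The in-frame share of these clonotypes did not depart from 1 in 3, although the interval also covers moderate departures. The share alone does not tell how the junctions were made or kept. In γδT, 44.96% of Vγ2 clonotypes over the same filter (214 of 476, 40.4% to 49.6%) and 36.0% of Vγ1.2 clonotypes (248 of 689, 32.4% to 39.7%) were in frame. The exact binomial p against 1 in 3 was 1.71e-07 for Vγ2 and 0.146 for Vγ1.2, so that the Vγ1.2 share of γδT did not depart from it either. Counted once over libraries, the same test gave 8.52e-06 and 0.581 for γδT. Per target and library, 23 of 71 Vγ2 ILC2 clonotypes (32.4%, 21.8% to 44.5%) and 29 of 94 Vγ1.2 ILC2 clonotypes (30.9%, 21.7% to 41.2%) were in frame. The Vγ2 intervals of the cell types overlapped.

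The out-of-frame Vγ2 clonotype CSYG*VE_SGFHKVF, with 4 inserted bases, had 2735 reads in ILC2 replicate 1, 2414 in ILC2 replicate 2, and 0 in ILC2 replicate 3 and both γδT libraries. It was singled out after its values were seen.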
